A study of Mus musculus with 3 samples.

How the data were processed

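Total RNA from pools of neural retinas of Rp1 knockout mice, each of 3 to 4 mice, was hybridised to 3 arrays. Per the labels, the arrays were of the mouse U74Av2 type. The deposited value table gives 1 intensity for each of 12488 probe sets on each array, on a linear scale. The method that turned probe intensities into these deposited values is not given in the sources used here. The deposited intensities had been brought to a common level, since the mean after leaving out the lowest and highest 2% of probe sets was 500.3, 500.3 and 500.2. These means differed by less than the 5% set as tolerance, so the values were used as deposited, with no further scaling. All intensities were above 0 (the lowest was 0.7), and log2 was taken with no pseudocount and no floor. Scanner files and detection calls were not used here. No pair of columns was identical (0 pairs). Because the deposited values were already scaled, a difference in total RNA between the pools cannot be seen in them.

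All 3 arrays belong to 1 group by their labels, so no comparison between groups was made. Replicate numbers follow the order of the samples and are names only. Gene symbols came from the platform annotation of the series, updated through the Entrez gene number against a RefSeq gene table (assembly GRCm38.p6), of which no coordinates were used. Of the 12422 probe sets other than controls, 10833 had 1 symbol, 396 had several and 1193 had none. The table held the gene number of 10817 of those with 1 symbol, and 0 symbols changed. A probe set with several symbols or none stayed in the tests and gave no gene name. A gene with several probe sets was represented by the one with the highest mean log2 signal, which gave 8251 genes.

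The gene lists, the tests and the rule for naming genes were set before the data were examined. The reference level of an array was the 90th percentile of the log2 signals of 95 probe sets of 82 measured genes (of 99 listed) known from other tissues, of which 7 were themselves called above it. Each probe set's log2 signal minus that level was tested against 0 with limma 3.58.1 in R 4.3.3 (intercept fit, empirical Bayes with a trend of the variance on signal), with Benjamini-Hochberg adjustment over 12422 probe sets and an adjusted p under 0.05. The prior carried 7.05 degrees of freedom and the test had 13.1 in total. The level was treated as known, so its own error is not in these p-values. Every "above" or "below" is relative to that level and is not a detection call.

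For each list, the number of measured members above the level was set against all other genes with a two-sided Fisher's exact test, adjusted over 25 lists. The lists covered photoreceptors, cones, photoreceptor fate factors, progenitors, cell cycle, bipolar, amacrine and horizontal, and ganglion cells, synapse, Müller glia and astrocytes, reactive gliosis, microglia, endothelium, red blood cells, pigment epithelium, lens, cornea with iris and sclera, microtubules and cilia, stress kinases, immediate early genes, apoptosis, clock, glycolysis, X-inactive and Y-linked genes, and housekeeping. Some genes are in more than 1 list. Counts adjusted over the list alone were the same as the counts printed except where stated.

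Spread between the pools was tested per probe set by the ratio of its variance (2 degrees of freedom) to a prior variance fitted robustly against mean signal in limma, upper tail. For lists with at least 3 members above the level, the 3 array means of the members' log2 deviations were computed, and their standard deviation was compared with 10000 random lists of the same size matched on mean log2 signal in 20 bins, two-sided in direction, adjusted over 22 lists. RNA controls were read as ratios of 3' to 5' control signals, and the hybridisation controls (BioB, BioC, BioD and Cre probe sets) as log2 deviations from their means.

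The rule for named genes took from each list the 5 members called above with the largest lowest-array signal and the 2 lowest members, the 20 highest genes outside the lists, the 20 named probe sets with the smallest spread p, and all X-inactive and Y-linked genes. Not all of these are named in the text.

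The procedures were tested on simulated data. With 12422 probe sets, the level test called 83% of those set 1 log2 unit above the level and 99% of those 2 units above. It called 5.9% of those set at the level. The simulated arrays all had the same level, whereas the measured levels were 223, 218 and 266. The simulated noise was drawn from the fitted prior, so these rates need not hold for the data. The spread test called 11% of probe sets given an added SD of 1 log2 unit and 58% at 2, and 0.0491% of the rest. The list spread test was run on 5951 probe sets with a mean above the level and lists of 12, and scored at an unadjusted p under 0.05. At that threshold it called 0% of lists given a common shift with an SD of 0.1, 100% at 0.2, and 3% with none. Probe sets were simulated independently, so the 3% does not cover lists whose genes vary together.

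Alternatives set before the data were examined were other reference levels (75th and 95th percentile, array median), quantile normalization, a prior without trend or robustness, a floor of 20, a signal above the level on all 3 arrays in place of the test, mean over a gene's probe sets, probe sets of plain type (identifier with no suffix for shared or family probes), loess for the spread of probe sets, and leaving out each pool in turn. A reference level from Bacillus and yeast control probe sets, loess for list spread, and a correction of each gene's deviation by that of its 20 nearest genes in signal were chosen after the data were seen. Figures were drawn with matplotlib 3.10.9.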

Results

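Gene expression was measured by microarray in neural retina of mice lacking Rp1, the gene of a microtubule-associated protein of photoreceptor outer segments. The mice were on a mixed 129/SvEv and C57BL/6 background and the retinas were taken on postnatal day 7, between 1 and 2 pm. Each of the 3 arrays was hybridised with RNA from its own pool of neural retinas from 3 to 4 mice. The 3 arrays, called pools 1, 2 and 3 here, form 1 group, and no wild-type retina was analysed here, so no value below is an effect of the genotype. The comparisons that the design allows are between the signal of a gene and a level measured on the same array, and between the 3 pools. The table gives 1 signal for each of 12488 probe sets, of which 66 are control probe sets. No depth applies to an array, and the number of arrays limits the precision.

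Rp1 itself was not analysed here, because 0 of the probe sets carried its symbol in the annotation used. The genotype therefore rests on the labels alone and has no check in the signals.

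Of 12422 probe sets tested, 5012 (40.3%) had a signal above the reference level, 5105 lay below it and 2305 were called neither way. The reference level of an array was the 90th percentile of the signals of probe sets for genes known from other tissues, such as liver, pancreas and muscle, and it was 223, 218 and 266 in pools 1 to 3. At the level of genes, 4013 of 8251 (48.6%) were above it, each gene taken by its probe set with the highest mean. Outside the gene lists, the tubulin gene Tuba1c had a signal of 38531 ± 1543 (SD, n = 3, as for all signals below), the ribosomal protein genes Rpl41 and Rps24 had 33761 ± 4473 and 27113 ± 3357, and the translationally controlled protein gene Tpt1 had 25464 ± 2383. The cytoplasmic actin gene Actg1 and the brain creatine kinase gene Ckb followed with 22231 ± 1943 and 20455 ± 2756. Housekeeping genes were above the level more often than other genes (odds ratio 7.41, 95% confidence interval 1.70 to 67.3, Fisher's exact test, adjusted p = 0.0128). Of 16 measured, 14 were above it. The elongation factor gene Eef1a1 (36057 ± 3560) and the ribosomal stalk gene Rplp0 (17804 ± 1475) were among them, while Gusb and Sdha were called neither way, and with probe sets of plain type alone the adjusted p was 0.0604. Probe sets differ in how strongly they bind, so these signals do not rank genes by transcript number, and each level is set against the reference level only.

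**Figure D1:**
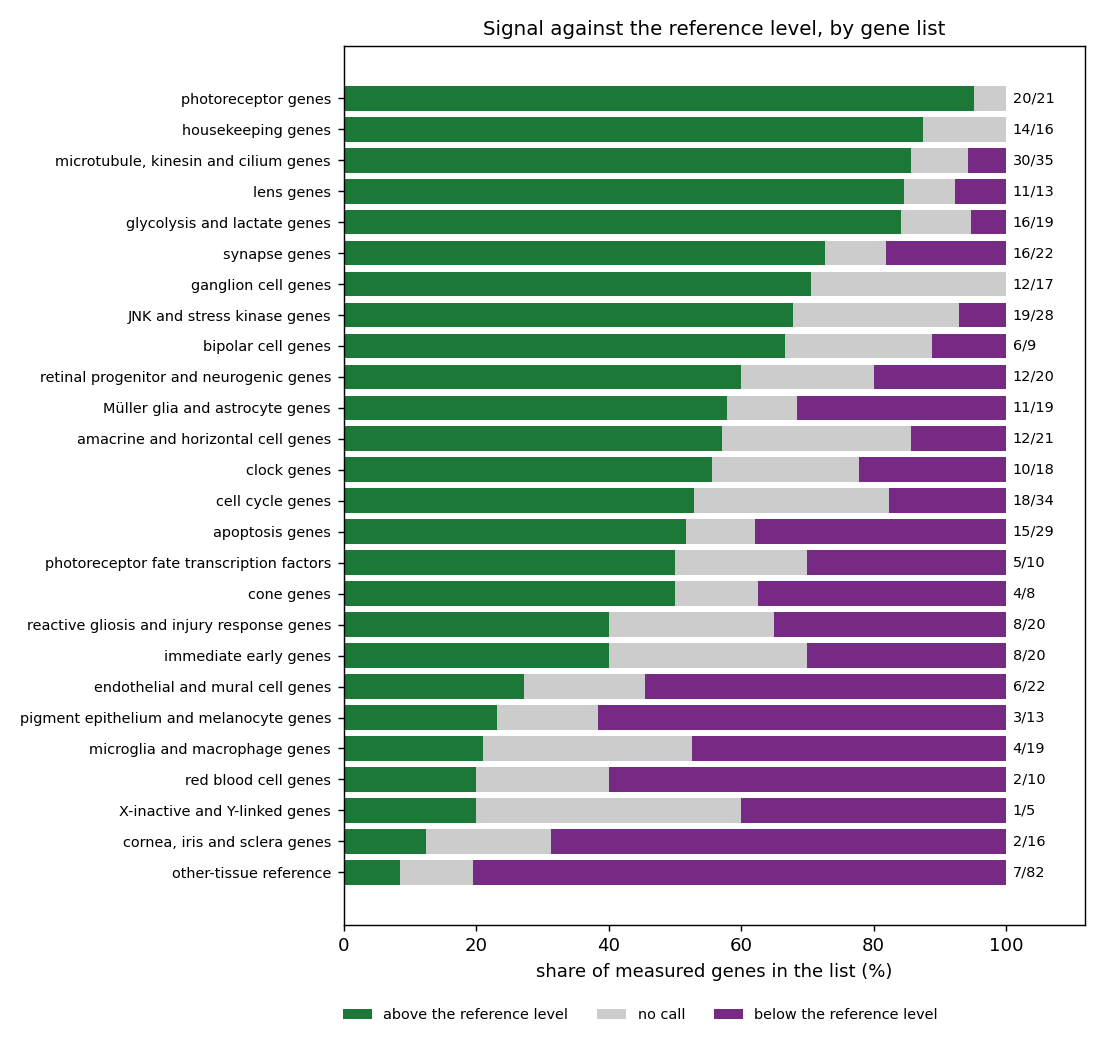
Share of the measured genes of each fixed list, in percent, whose signal over the 3 arrays was above the reference level (green), below it (purple) or called neither way (grey), with the number above and the number measured at the right. Photoreceptor genes reached 20 of 21 and the other-tissue genes that set the level 7 of 82.

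Photoreceptor genes were above the reference level in 20 of 21 measured cases, and 20 were also above when adjusted over the list alone. They were above it more often than other genes (odds ratio 21.2, 95% confidence interval 3.39 to 876, Fisher's exact test, adjusted p = 0.00011). Phosducin (Pdc), a binding partner of the transducin beta-gamma subunits, had a signal of 18849 ± 1922, which is 6.32 ± 0.27 (SE) above the reference level on the log2 scale. Arrestin (Sag), which ends rhodopsin signalling, had 15240 ± 2318 (log2 6.01). Prom1, needed for outer segment discs, had 8714 ± 698 and Tulp1, a photoreceptor transport gene, 8364 ± 227, which are log2 5.21 and 5.15 above the level. Gnb1, the rod transducin beta subunit gene, had 8861 ± 672 (log2 5.23). The lowest members were the guanylate cyclase gene Gucy2e at 213 ± 65.6, called neither way, and the rod phosphodiesterase gene Pde6a at 345 ± 28.2 (log2 0.55, adjusted p = 0.0215). Pde6a lay on the other side, at log2 -0.17, with the 95th percentile as the reference level.

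Transcription factors of photoreceptor fate were above the level in 5 of 10 cases (Fisher's exact test, adjusted p = 1). Crx, the regulator of photoreceptor genes, had 7787 ± 864 and Neurod1 7838 ± 1068, both log2 5.05 above the level. Mef2d had 7025 ± 614, Prdm1 1679 ± 251, and the rod factor Nrl 456 ± 49.0 (log2 0.95, adjusted p = 0.000246). The orphan receptor gene Esrrb (61.3 ± 32.1) and the thyroid hormone receptor gene Thrb (73.5 ± 32.7) were below it. Cone genes were above in 4 of 8 cases (Fisher's exact test, adjusted p = 1). These were Gnb3 (5027 ± 500), the S opsin gene Opn1sw (1592 ± 171), the cone transducin gene Gnat2 (1049 ± 108) and Gngt2 (794 ± 77.3). The channel gene Cnga3, at 45.0 ± 32.3, was below.

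Genes of progenitors and of the cell cycle were above the level in part. Of 20 measured progenitor and neurogenic genes 12 were above and 4 below (Fisher's exact test, adjusted p = 0.587). Fabp7, a fatty acid binding protein of radial glia, had 8302 ± 352 (log2 5.14), and the eye field factors Pax6 and Rax had 2283 ± 200 and 1778 ± 136. Sox2 had 1802 ± 174 and Hes6 1817 ± 173. Atoh7, needed for ganglion cell birth, had 31.3 ± 14.3 and Fgf15 51.1 ± 49.5, both below the level. Of 34 cell cycle genes 18 were above, 6 below and 10 neither (Fisher's exact test, adjusted p = 0.831), and 17 were above when adjusted over the list alone. The kinase gene Cdk4 had 3107 ± 644, the cyclin gene Ccnd1 2038 ± 334, the inhibitor gene Cdkn1c 1963 ± 342 and the replication genes Pcna and Mcm7 1153 ± 52.5 and 1100 ± 117. Mcm6 (21.8 ± 6.3) and Ccne2 (42.9 ± 27.3) were below. With the 95th percentile as the reference level 10 cell cycle genes were above.

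**Figure D2:**
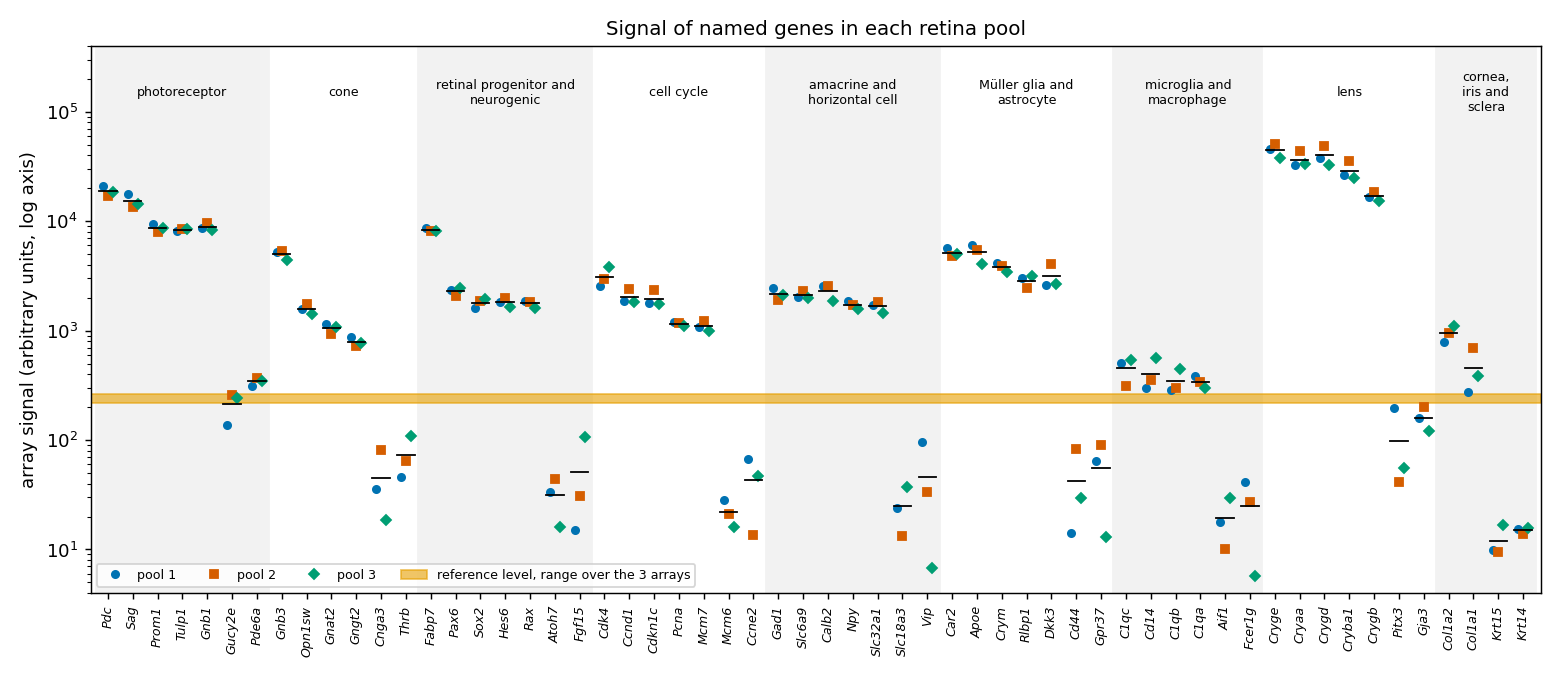
Array signal (arbitrary units, log axis) of genes named by the fixed rule in 9 lists, with pool 1 as circles, pool 2 as squares, pool 3 as diamonds and the mean as a bar. The band spans the reference levels of the 3 arrays, 218 to 266. Pdc, Sag and the crystallins lie far above it, and Atoh7, Aif1 and Krt14 lie below it.

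None of the 3 lists of inner retinal neurons passed the list test. Amacrine and horizontal cell genes were above in 12 of 21 cases (Fisher's exact test, adjusted p = 0.643). Among them the GABA synthesis gene Gad1 had 2154 ± 278, the glycine transporter gene Slc6a9 2109 ± 156, calretinin (Calb2) 2323 ± 408, Npy 1721 ± 139 and the vesicular transporter gene Slc32a1 1663 ± 189. Slc18a3, the vesicular acetylcholine transporter gene, had 24.8 ± 11.8 and Vip 45.8 ± 46.2, both below. Ganglion cell genes were above in 12 of 17 cases, with 0 below (Fisher's exact test, adjusted p = 0.195). Uchl1 had 3008 ± 124, Stmn2 2779 ± 352, the intermediate filament gene Ina 2681 ± 160, the growth cone gene Gap43 1951 ± 380 and Isl1 1021 ± 173. Eomes (157 ± 47.7) and Ebf1 (189 ± 73.7) were called neither way. Bipolar cell genes were above in 6 of 9 cases (Fisher's exact test, adjusted p = 0.587), among them Gnao1 (4489 ± 1251), Gnb5 (766 ± 165), Pcp2 (649 ± 131) and Rgs11 (435 ± 35.1). Prkca, the protein kinase C gene of rod bipolar cells, was called neither way at 276 ± 57.1.

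Synapse genes were above the level in 16 of 22 cases and below it in 4 (odds ratio 2.82, Fisher's exact test, adjusted p = 0.0968). The release genes Snap25 and Vamp2 had 7758 ± 1113 and 4029 ± 1086, the ribbon gene Ctbp2 3485 ± 709, the calcium sensor gene Syt1 2584 ± 456 and the glutamate receptor gene Gria2 2038 ± 425. Bassoon (Bsn), at 66.6 ± 62.3, and Vamp1, at 83.7 ± 75.3, were below. With probe sets of plain type alone the list passed (16 above, adjusted p = 0.0372), and with the 95th percentile 10 members were above.

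Müller glia and astrocyte genes were above the level in 11 of 19 cases and below it in 6 (Fisher's exact test, adjusted p = 0.643). Apoe had 5231 ± 1049, the carbonic anhydrase gene Car2 5169 ± 438, Crym 3824 ± 380, Dkk3 3133 ± 814 and the retinaldehyde binding protein gene Rlbp1 2866 ± 384. Cd44 (42.3 ± 36.3) and Gpr37 (55.9 ± 39.4) were below. Reactive gliosis and injury response genes were above in 8 of 20 cases (Fisher's exact test, adjusted p = 0.643). Haem oxygenase (Hmox1) had 1567 ± 351, ceruloplasmin (Cp) 1057 ± 69.6, Stat3 987 ± 236, Mt2 801 ± 17.5 and Timp1 622 ± 130. Lgals3 (12.1 ± 7.6) and Fgf2 (31.9 ± 34.0) were below the level.

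Cornea, iris and sclera genes were above the level in 2 of 16 cases, less often than other genes. The odds ratio was 0.15 (95% confidence interval 0.0166 to 0.656, Fisher's exact test, adjusted p = 0.0218). The 2 were the collagen genes Col1a2 (949 ± 162) and Col1a1 (452 ± 214), and the keratin genes Krt14 (15 ± 1.0) and Krt15 (12 ± 4.1) were below. This call was lost without pool 1 (adjusted p = 0.0782), with each array's median as the level (0.0611) and with a signal above the level on all 3 arrays in place of the test (0.0542). Pigment epithelium and melanocyte genes were above in 3 of 13 cases (Fisher's exact test, adjusted p = 0.195), namely Ptgds (1634 ± 183), Pmel (436 ± 91.7) and Dct (391 ± 144). Tyr and Stra6 had 66.1 ± 30 and 65.1 ± 38.5. Endothelial and mural cell genes were above in 6 of 22 cases (Fisher's exact test, adjusted p = 0.141), among them the basement membrane collagen genes Col4a1 (1855 ± 404) and Col4a2 (1544 ± 283), Sparc (2019 ± 707), the VEGF receptor gene Kdr (1367 ± 312) and Eng (553 ± 87.7). Nos3 and Icam2 had 22.4 ± 5.4 and 27.9 ± 13.1. Red blood cell genes were above in 2 of 10 cases (Fisher's exact test, adjusted p = 0.212), the globin genes Hba-a1 (6411 ± 796) and Hbb-b2 (1714 ± 324), whose near-identical copies may share probes.

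Microglia and macrophage genes were above the level in 4 of 19 cases (odds ratio 0.281, Fisher's exact test, adjusted p = 0.0711). These were the complement genes C1qc (451 ± 123), C1qb (345 ± 90.3) and C1qa (340 ± 42.9) and the receptor gene Cd14 (405 ± 135), while Aif1, at 19.3 ± 9.9, and Fcer1g, at 24.7 ± 17.9, were below. The count was 9 at the 75th percentile and 0 at the 95th, where the list had fewer members above than other genes (adjusted p = 0.00145). It was 2 without pool 2 (adjusted p = 0.0091) and 3 without pool 1 (adjusted p = 0.0393), and the list then passed too, as it did without the trend (2 above, adjusted p = 0.0094) and with plain probe sets (3 above, adjusted p = 0.0372).

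Lens genes had some of the highest signals on the arrays. Of 13 measured, 11 were above the level (odds ratio 5.82, 95% confidence interval 1.27 to 54.0, Fisher's exact test, adjusted p = 0.0455). The crystallin genes Cryge (44748 ± 6919, log2 7.56), Crygd (40052 ± 8330), Cryaa (36580 ± 5998), Cryba1 (28861 ± 5594) and Crygb (16855 ± 1465) led the list. Crystallins are the main proteins of lens fibres, and some are known from retina as well. The 11 genes above the level were 9 crystallins and 2 other lens genes, Bfsp1 and Mip. Gja3, a lens gap junction gene, was called neither way at 160 ± 40.9 and Pitx3, a lens transcription factor gene, had 97.4 ± 85.0. The gamma crystallin genes are near-identical, so their probes may share transcripts, and with probe sets of plain type alone 8 of 12 lens genes were above (adjusted p = 0.478). The list call was also lost under 5 other settings, among them the 75th percentile as the level (adjusted p = 0.204).

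Microtubule, kinesin and cilium genes, the family of functions to which the product of Rp1 belongs, were above the level in 30 of 35 cases. Their odds ratio was 6.38 (95% confidence interval 2.45 to 21.1, Fisher's exact test, adjusted p = 0.00011). The tubulin genes Tuba1a, Tubb5 and Tubb3 had 33597 ± 4819, 14186 ± 603 and 7256 ± 951, with shared probes possible within this family. The tubulin-binding stathmin gene Stmn1 had 12308 ± 1857 and the dynein light chain gene Dynll1 10479 ± 970. Dynlt1b (36.5 ± 4.5) and Pcnt (80.0 ± 103) were below. Glycolysis and lactate genes were above in 16 of 19 cases, and 17 when adjusted over the list alone. For the 16 the odds ratio was 5.65 (95% confidence interval 1.62 to 30.3, Fisher's exact test, adjusted p = 0.0128). Lactate dehydrogenase (Ldha) had 17075 ± 1899, pyruvate kinase (Pkm) 13744 ± 1312, Aldoa 9670 ± 754, Tpi1 6625 ± 523 and Pgk1 6547 ± 699.5. The monocarboxylate transporter gene Slc16a1 was below at 45.1 ± 40.9.

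JNK and stress kinase genes were above the level in 19 of 28 cases (Fisher's exact test, adjusted p = 0.141). Jund had 10319 ± 759, Rac1 6677 ± 706, Map3k1 2223 ± 655, Cdc42 1855 ± 93.9 and the JNK1 gene Mapk8 1595 ± 315. Map3k11 (93.5 ± 67.6) and Crk (90.8 ± 4.1) were below. Apoptosis genes were above in 15 of 29 cases and below in 11 (Fisher's exact test, adjusted p = 0.927). Pdcd4 had 2491 ± 469, the survival genes Bcl2l1 and Mcl1 1644 ± 113 and 1135 ± 93.8, Casp2 1167 ± 110 and Aifm1 1233 ± 188. The death receptor gene Fas and Casp8 were below the level.

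Immediate early genes were above the level in 8 of 20 cases (Fisher's exact test, adjusted p = 0.643). Btg2 had 3789 ± 555, Ier3 1522 ± 153, the phosphatase gene Dusp1 617 ± 29.4, Jun 553 ± 35.1 and Ier2 511 ± 76.0, while Klf2 (28.6 ± 6.2) and Ccn2 (44.4 ± 55.4) were below. Clock genes were above in 10 of 18 cases (Fisher's exact test, adjusted p = 0.762). The core activator gene Arntl had 1941 ± 216, the repressor genes Cry1 and Nr1d2 1040 ± 104 and 978 ± 118, and the kinase genes Csnk1d and Csnk1e 2307 ± 290 and 900.4 ± 101.1. Per2 (54.5 ± 35.6) and Npas2 (21.8 ± 3.7) were below. All retinas were collected within the same hour of the day, so a cycle over the day was not measured.

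Several genes had probe sets that disagreed. Of 2073 genes with more than 1 probe set, 595 had one above and one below the level, and among the list genes these were 43 of 144. Of the genes named, Pdc, Apoe, Bcl2l1, Col1a1, Col1a2, Cry1, Csnk1d, Cryge, Gnao1, Gria2, Map3k1, Mapk8, Rgs11, Stmn1, Stmn2, Timp1 and Rps24 had another probe set below the level.

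The 3 pools gave close signals for probe sets called above the reference level, a call that itself favours a small spread between the pools. Over the 5012 probe sets above it, Pearson's r of the log2 signals was 0.951 between pools 1 and 2, 0.943 between 1 and 3 and 0.953 between 2 and 3, across probe sets, which are not independent replicates. The median absolute log2 differences were 0.23, 0.24 and 0.22, and 1.70%, 2.49% and 1.28% of these probe sets differed over 2-fold. Over all 12422 probe sets the correlations were 0.906, 0.913 and 0.908, and 22.3%, 21.7% and 21.6% differed over 2-fold. The coefficient of variation had a median of 13.9% above the level (quartiles 8.74% and 20.8%) and 40.5% for the rest. The labels say that each pool held several mice but not whether the pools shared litters. The p-values of the level test and of the spread test per probe set rest on these 3 pools and a prior over probe sets. Fisher's exact test and the random lists set genes against other genes. Their p-values do not measure replication across pools.

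The RNA controls differed between the pools. The ratio of the 3' to the 5' control probe set was 1.53, 1.40 and 1.28 for beta-actin and 0.877, 0.905 and 0.789 for Gapdh in pools 1, 2 and 3. The 9 hybridisation control probe sets for bacterial and phage genes, which are not mouse transcripts, were highest in pool 2 for 8 and lowest in pool 3 for 9, with mean log2 deviations of 0.01, 0.22 and -0.24 in pools 1, 2 and 3. The actin gene probe sets did not follow the actin control. The 3' control of Actb was 18922, 30348 and 23942, while the gene's other probe sets read 11832, 7696 and 4847 and 6981, 3698 and 2805.

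Xist, the RNA that coats the inactive X chromosome in female cells, had the smallest p for spread between the pools of all probe sets. It read 686 in pool 1, 1682 in pool 2 and 12 in pool 3 (limma-based variance test, F = 103, adjusted p = 0.0766), so it did not pass the correction. The Y-linked gene Eif2s3y was above the reference level in the pools, at 656, 460 and 569 (mean log2 1.24 above, adjusted p = 2.28e-05), Kdm5d and Sry were below it at means of 95.6 and 138, and Uty was called neither way at 161. In this list of 5 X-inactive and Y-linked genes 1 was above (Fisher's exact test, adjusted p = 0.587), and with probe sets of plain type alone 0 of 4 were. The next smallest p-values among named probe sets were those of Msi1 (30.1, 369 and 673), Nedd4 (466, 514 and 28.6), Klk1b22 (21.4, 404 and 475), Tmem129 (115, 667 and 806) and Krt86 (244, 833 and 1285). Prph2, a photoreceptor disc gene, read 2684, 6922 and 7289. No probe set passed in the limma-based test of excess spread (0 of 12422). An unadjusted p under 0.05 was reached by 508, against 621 expected under the fitted prior. That prior was fitted to these same variances, so the count cannot show whether the pools differed in general. The test sets a probe set only against others of like signal. Among the 5951 probe sets with a mean above the level alone, 7 passed, namely Xist (adjusted p = 4.39e-05), Krt86, Tmem129, F2r, Ica1 and 2 without a gene name.

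Lens genes varied together between the pools. Their 11 members above the level deviated from their own means by -0.07, 0.24 and -0.17 log2 on average in pools 1, 2 and 3, which is 1.33-fold between pools 2 and 3. The standard deviation of these means was 0.217. Of random lists of equal size, matched on signal in 20 bins, 95% stayed under 0.128 (permutation test, p = 0.0002, adjusted p = 0.0044). Few genes outside the list are as bright as the leading crystallins, so the matching is loose for these. Gamma crystallin probes may share transcripts, so the members may not be separate values and the p may be too small. Pool 2 had the highest signal for 10 of the 11 genes and pool 3 the lowest for 9. The hybridisation controls moved in the same direction, with a log2 difference between pools 2 and 3 of 0.46 ± 0.07 (SE, 9 controls) against 0.42 ± 0.11 (SE, 11 genes) for the lens genes. Each control transcript has more than 1 of these probe sets, so the 9 controls are not independent values. The spread rested on pool 2, since without it the standard deviation was 0.074 (adjusted p = 0.732). It also missed the threshold with quantile normalization (0.119, adjusted p = 0.184), with loess (adjusted p = 0.0689), with a correction for signal (adjusted p = 0.122) and with all 13 measured members (adjusted p = 0.181).

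Synapse genes were lowest in pool 2. Their 16 members above the level deviated by 0.13, -0.18 and 0.05 log2 in pools 1, 2 and 3, a 1.23-fold range (standard deviation 0.157 against 0.111 for random lists, permutation test, adjusted p = 0.0374). Pool 2 had the lowest signal for 8 of the 16 genes. The call was lost without pool 1 (adjusted p = 0.119) or pool 2 (0.732), with the median of the members (0.375), with all members (0.110), and with quantile normalization (0.0528), loess (0.0689) or a correction for signal (0.122). Ganglion cell genes had nearly the same deviations, 0.13, -0.17 and 0.04, and cell cycle genes had -0.15, 0.12 and 0.03. Neither passed (permutation test, adjusted p = 0.0858 for each list). Progenitor genes deviated by -0.12, 0.10 and 0.02 (adjusted p = 0.374). Amacrine and horizontal cell genes, also neuronal, deviated by -0.03, 0.06 and -0.03 (adjusted p = 0.892). The other 16 of the 22 lists tested had adjusted p of 0.374 or more, among them photoreceptor genes (0.394), microglia genes (0.374) and the microtubule list (0.931). The red blood cell, cornea and X-inactive and Y-linked lists had fewer than 3 members above the level and were not tested for spread.

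**Figure D3:**
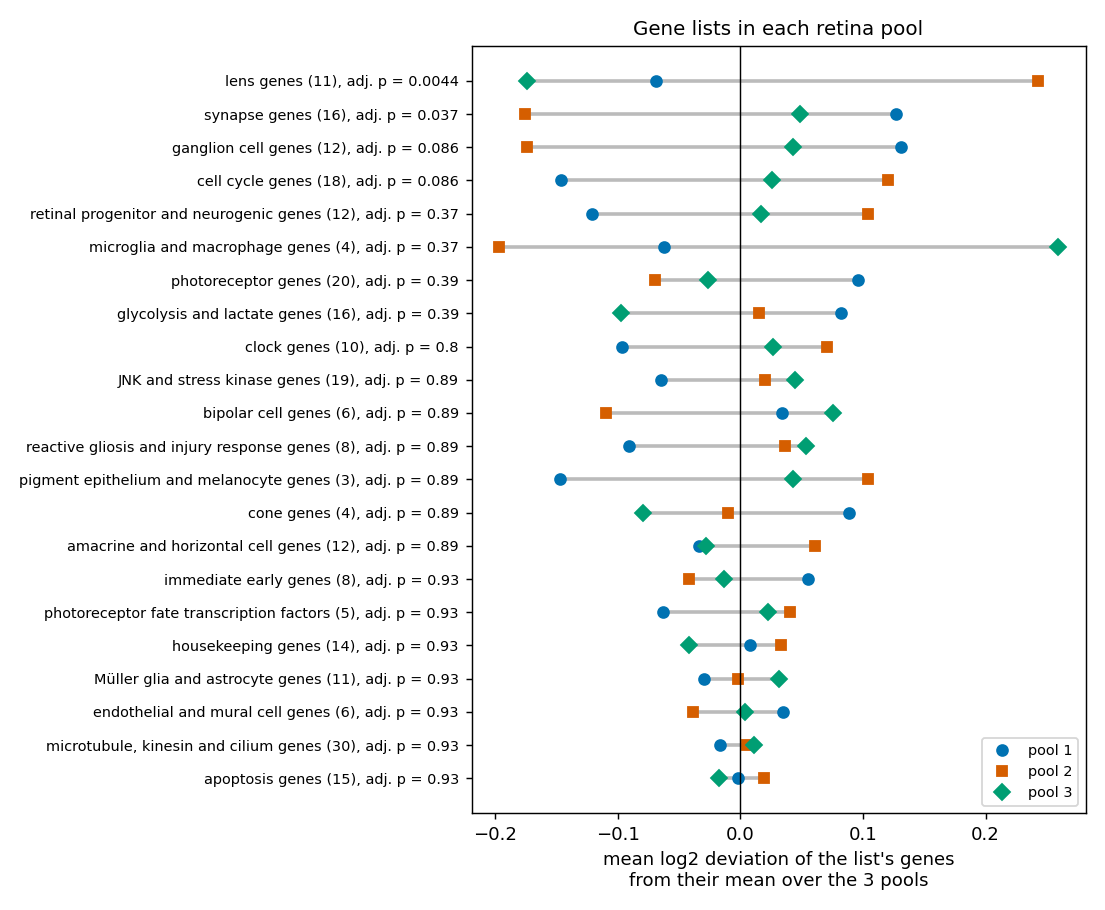
Mean log2 deviation of each list's genes above the reference level from their own means over the 3 pools, with pool 1 as circles, pool 2 as squares and pool 3 as diamonds, the number of genes in brackets and the adjusted permutation p. Lens genes were highest in pool 2 (0.24) and lowest in pool 3 (-0.17), and synapse genes were lowest in pool 2 (-0.18).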

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

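The number of probe sets above the reference level stayed within 1.5 times of 5012 under every alternative run, from 3756 at the 95th percentile to 7208 with the Bacillus and yeast control level, which was added after the data were seen, and 4756 to 4955 with 1 pool left out. Of 199 named probe sets, 199 kept their side and call with quantile normalization, 198 with the array median or a floor of 20, 189 without the trend, 187 to 190 with a pool left out, 178 at the 95th percentile, 177 at the 75th and 160 with the Bacillus and yeast level. The median coefficient of variation was 40.5% for probe sets not called above the level against 13.9% for those called above it. The call uses the spread between the same arrays, so part of this contrast follows from the split. Signs turned for Pde6a (-0.17), C1qb (-0.20), C1qa (-0.19) and Dct (-0.0621) at the 95th percentile, for Sry (0.17) at the 75th, and for Grik1 (0.41), Map3k11 (0.0084), Crk (0.22) and Sry (0.79) with the Bacillus and yeast level, since a higher or lower level moves every value. At the 95th percentile the members above were 10 for cell cycle, 0 for microglia, 1 for pigment epithelium, 1 for cornea, 5 for immediate early, 9 for apoptosis and 10 for synapse genes. At the 75th percentile they were 9 for microglia and 4 for red blood cell genes. With the Bacillus and yeast level they were 10 for microglia, 4 for red blood cell, 5 for pigment epithelium, 5 for cornea, 14 for immediate early, 13 for reactive gliosis and 2 for X-inactive and Y-linked genes. Without the trend they were 2 for microglia and 1 for cornea genes, with probe sets averaged 0 for cornea genes, and with probe sets of plain type 1 for cornea and 0 for X-inactive and Y-linked genes. With each pool left out in turn the count ranged from 2 to 4 for microglia (2 without pool 2) and from 1 to 2 for X-inactive and Y-linked genes (2 without pool 3). Fewer arrays were then used, and for the other settings the cause was not tested.

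The lens list call was lost at the 75th percentile (adjusted p = 0.204), the array median (0.0933), the Bacillus and yeast level (0.182), a signal above the level on all 3 arrays (0.0956), probe sets averaged (0.0629) and plain probe sets (0.478), with 8 to 12 members above throughout. The pigment epithelium list passed as having fewer members above at the 75th percentile (0.0348). The ganglion cell and stress kinase lists passed with the Bacillus and yeast level (0.0112 and 0.0115), the ganglion cell list also with probe sets averaged (0.0218), and the microglia list passed at the 95th percentile, without the trend (0.0094), without pool 1 (0.0393) or pool 2 (0.0091), and with plain probe sets (0.0372). Calls of excess spread stayed at 0 under the other alternatives and were 7 over probe sets with a mean above the level, where fewer, less noisy probe sets were tested. The standard deviation of lens genes between the pools was 0.192 with all measured members, 0.119 with quantile normalization, 0.148 with loess and 0.148 with the correction for signal, all short of the threshold, and 0.074 to 0.294 with a pool left out. That of synapse genes was 0.102 with the median of the members, 0.241 with all members, 0.155 with quantile normalization, 0.156 with loess and 0.140 with the correction, again short of the threshold, and 0.0553 to 0.213 with a pool left out. Cell cycle genes passed with probe sets averaged (0.169, adjusted p = 0.0477) and without pool 3 (0.0275), with a range of 0.0671 to 0.188, and ganglion cell genes without pool 3 (0.022), with a range of 0.0627 to 0.216. The cause of these changes was not tested. The median absolute log2 difference between arrays, 0.40 on average, was 0.25 over probe sets with a mean above the level and 0.39 to 0.41 for the single pairs. No paired analysis was possible because there is 1 group.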

Other observations

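All tests of explanations in this part were chosen after the results were seen, and the bound in the test of lens tissue was raised from 1 to 2 standard errors after its value was known, which changed its reading from a match to undecided. The test of a lower share of neurons was likewise required, after its value was known, to hold without the microglia genes, which changed its reading from excluded to undecided. The standard errors in this part are over genes or control probe sets. Such members are not independent replicates, and each pool is 1 array. Bounds in standard errors therefore describe the members and not the variation between pools.

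Synapse and ganglion cell genes had deviations opposite in sign to those of cell cycle and progenitor genes in pools 1 and 2, although of these 4 lists synapse genes alone passed the test of spread. The 28 synapse and ganglion cell genes above the level deviated by 0.13, -0.17 and 0.05 log2 in pools 1, 2 and 3, and the 30 cell cycle and progenitor genes by -0.14, 0.11 and 0.02, with 24 of these 30 above their mean in pool 2. The standard deviation of the difference was 0.277, against 0.117 for the 95th percentile of random lists (permutation p = 1e-04, the smallest that 10000 lists can give), but the lists were picked after their deviations were seen, so this p is not independent evidence. Not every neuronal list took part, since amacrine and horizontal cell genes were higher in pool 2 than in pool 1, with a log2 difference of pool 1 minus pool 2 of -0.09 ± 0.12 (SE, 12 genes), and so were photoreceptor fate factors (-0.10 ± 0.15, SE, 5 genes).

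The opposition of synapse and ganglion cell genes to cell cycle and progenitor genes was weighed against 3 explanations. After correction for the 20 nearest genes in signal its standard deviation was 0.264, against 0.277 before, so this correction for a signal-dependent difference between arrays removed little of it. The value lay above the 0.122 of random lists. Because the lists were picked for their opposition, that comparison is not independent evidence about the cause. A lower share of neurons would raise other cell types alike, but in pool 2 the mean deviation of glia, endothelial and microglia genes (21 genes) minus that of the cell cycle and progenitor genes was -0.163 ± 0.067 (SE), and without the microglia genes -0.129 ± 0.073 (SE, 17 genes), under 2 standard errors, so this explanation stays open too, the more so as the cell cycle and progenitor lists were picked for being high in pool 2. A difference in developmental stage between the pools was not decided, since photoreceptor and bipolar genes differed between pools 1 and 2 by 0.147 ± 0.093 (SE, higher in pool 1 in 15 of 25 genes), while the amacrine and fate factor lists leaned the other way, all under 2 standard errors. Both the mice in each pool and the handling of the tissue stay open as untested sources.

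The higher signal of lens genes in pool 2 could come from lens tissue carried over at dissection, from the scale of bright probe sets (the 30 brightest genes outside the list deviated by -0.02, 0.11 and -0.08 in pools 1, 2 and 3) or from hybridisation. The 9 hybridisation controls, which are not mouse transcripts, moved by a like amount. The log2 difference between pools 2 and 3 of the lens genes minus that of the controls was -0.0447 ± 0.128 (SE). A hybridisation difference shared with the controls therefore stays open. A scale factor common to a whole array would move every list alike. Housekeeping genes deviated by only 0.01, 0.03 and -0.04 in pools 1, 2 and 3, which argues against such a factor for the lens genes. The correction for signal took the standard deviation of the lens genes from 0.217 to 0.148, above the 0.113 of the 95th percentile of random lists. The adjusted p over 22 lists became 0.122 (permutation test), so the call was lost. The lens list was singled out by its smallest p among these lists. The correction also drew on genes outside the list, few of which are as bright as the leading crystallins. A trend with signal was therefore not decided. Carry-over would raise lens genes other than crystallins too, and Bfsp1, Mip and Gja3 deviated by 0.275 ± 0.220 (SE, 3 genes) in pool 2, which decides nothing, while 9 of 9 crystallins were above their mean there (0.246 ± 0.038 SE). Crystallin transcripts made in the retina itself stay open, and no biological explanation was tested.

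Xist read 686 in pool 1, 1682 in pool 2 and 12 in pool 3, where it was under that array's reference level of 266. The sex of the pooled mice is a candidate explanation. A pool with fewer females would have more Y-linked transcript. Eif2s3y in pool 3 stood only 0.0504 log2 above the mean of the other pools, against an expected SD of 0.263 for a single array. The error of such a difference is larger still, so the test cannot separate a small from no difference. Eif2s3y was lowest in pool 2, where Xist was highest, but it was highest in pool 1. The Eif2s3y signal also came from a probe set that is not of plain type, which limits it as a Y-linked marker. The sexes of the mice are not stated in the labels used here.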
